A study of Mus musculus with 9 samples.

How the data were processed

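H3K27me3 was profiled by chromatin immunoprecipitation sequencing in 8 libraries from lineage-negative, c-Kit-positive mouse bone marrow cells, 2 for each combination of genotype and treatment, and 1 input library was sequenced beside them. Per the labels, chromatin was fixed with formaldehyde and the libraries were read on an Illumina NovaSeq instrument. The tools bcl2fastq 2.20 and BWA 0.7.12 and the mouse build mm10 are named, without their roles, per the submitters' processing notes. The interval caller, its settings, the read filters, any adjustment for depth and the use made of the input are not given in the sources used here. No interval list of the input library was analysed here.

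Per the file headers, the deposited data hold an interval list and a list of interval summits for each library, on mm10, and a list of merged regions over all libraries. Intervals were therefore called per library by the authors and not on pooled replicates. The value of each summit is a score, the summit height, which the authors deposited as a whole number without a stated unit. It is the authors' own value and was used here to describe, rank or filter intervals. Heights may not be comparable between libraries, and the minimum height used as an alternative is a single value for all of them, so that it removes more intervals from some libraries than from others (38.8% were kept in RH VEH 1 and 62.1% in WT MET 2). Interval edges lie on a grid of 200 bp, and the smallest gap between neighbouring intervals was 800 bp in every library. The number of reads per library is unknown, so no counting interval could be given for an interval or its absence, and the number of intervals per library stands in for depth only loosely. A library without an interval at a place can still carry the mark there below the caller's limit.

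Intervals of the 8 libraries were merged where they overlapped by at least 1 bp. This gave 18556 regions, of which 18556 were identical to the deposited merged regions. A region or gene was called in a library where an interval overlapped it by at least 1 bp. In comparisons of 2 libraries with 2, a region or gene was counted where both libraries of a group called it and neither of the other did. The same count was made for the other splits of the same 4 libraries. Over 4 libraries against 4, regions called in all of a class and none of the other were counted and compared with the 35 splits of the 8 libraries. Interval number, covered length and further totals per library were compared by exact permutation, two-sided, over 70 assignments of 4 against 4. The smallest p this allows is 0.0286, against 0.333 for 2 against 2. Overlap was measured with the Jaccard index of covered base pairs for the 28 pairs of libraries, and tested one-sided over the 35 splits. Benjamini-Hochberg adjustment was applied within each family of tests, with a threshold of 0.05. The labels call the libraries replicates without saying that they came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

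Groups, tests, gene lists and most alternatives were set before the data were examined. The 15 lists covered Hox clusters, developmental regulators of other tissues, stem cell and self-renewal genes, myeloid, erythroid and megakaryocyte, lymphoid, and mast cell, basophil and eosinophil genes, stromal and endothelial genes, inflammatory genes, cell cycle inhibitors and tumour suppressors, mitochondrial complex I genes, methionine and one-carbon cycle genes, histone and DNA methylation machinery, housekeeping genes and imprinted genes. Of 413 list genes, 412 were matched to a reference gene table of the same build (GRCm38.p6, the assembly of mm10), and Ahsp was not. The planned test of promoters within 2500 bp of a transcription start was not run, because the table used here gives gene spans without strand. Overlap with the gene span, which had been listed as an alternative, took its place, and the nearest gene span took the place of the nearest transcription start. A test of values per region was planned only for files that hold such values and was not run. List counts per library were compared by exact permutation, and list genes among changed genes by Fisher's exact test against all genes called in at least 1 of the libraries compared.

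The rule for named genes took, in each comparison of 2 with 2, the 10 widest changed regions per direction with the gene they overlap or the nearest one, up to 4 changed list genes per list and direction in alphabetical order, and the anchors Hoxd11, Pax6, Gata4, Pax5, Cdkn2a, Meis1, Actb and Gapdh. Width was that of the region merged over all 8 libraries. Of those 10 regions, the ones at or next to protein-coding genes are named in the text, except for a few that are not reported here. Other settings chosen beforehand were a minimum summit height of 15, the median of all intervals, autosomes alone, cover of at least 50% of a region, intervals within 1000 bp joined, 2000 bp bins, a block on replicate number, labels permuted within the other factor, and each library left out in turn. An equal number of 11620 intervals per library, taken by summit height, and gene spans with flanks of 2500 bp were added after the data were seen. Use of the minimum summit height on genes had not been planned either. The planned Fisher's exact test of the regions lost in RH VEH against other regions with the same number of WT MET calls was set aside, because the former have 2 WT VEH calls by definition and the latter 0 or 1. Shares at the same number of WT libraries calling took its place and, like the overlaps expected among regions that could be in both lists, were added after the data were seen. Summit heights are often equal, and the order of equal heights in the equal-number alternative was changed from file order to a seeded random draw after its first values had been seen. File order and 9 further draws, 10 orders in all, are given beside it.

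The count of changed regions was tested on simulated data before use. In a simulation of RH VEH against WT VEH on 6597 regions, with 200 regions changed each way, 159 lost regions (79.5%) and 124 gained regions (62%) were recovered, and 259 other regions were called. It used only regions called in all 8 libraries, complete changes, and misses drawn independently for each library. The changed regions of the data were weaker, so these figures do not give recovery or false calls for them. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, the Jaccard index came from bedtools 2.31.1, and plots were drawn with matplotlib 3.10.9. Coordinates are 1-based on mm10.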

Results

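H3K27me3, the trimethyl mark that Polycomb repressive complex 2 places on lysine 27 of histone H3 at silenced genes, was mapped in uncultured hematopoietic progenitors of mouse bone marrow, stem cells included, that were enriched as lineage-negative and c-Kit-positive. The cells came from female mice that had received a transplant and then vehicle (VEH) or metformin (MET), a biguanide that inhibits mitochondrial complex I, for 1 month. They were wild type (WT) for Dnmt3a, which encodes a de novo DNA methyltransferase, or carried its R878H allele (RH), both on an Mx1-cre background. The series title places the work in the question of whether metformin reduces the competitive advantage of R878H cells. Each of the 4 groups had 2 libraries. WT VEH 1 and 2 held 12009 and 16259 intervals, WT MET 1 and 2 held 16572 and 16694, RH VEH 1 and 2 held 11620 and 13339, and RH MET 1 and 2 held 16879 and 15257.

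Most classic Polycomb targets carried the mark in every library. Hoxd11, a homeobox gene of the limb and axis, and Cdkn2a, which encodes the cell cycle inhibitors p16 and p19, were covered over 100% of their spans in all 8 libraries. Pax6, a regulator of eye and brain development, was covered over 89.8% to 96.6%, and Gata4, a regulator of heart and endoderm, over 84.9% to 100%. Pax5, the B-lineage factor, ranged from 28.9% to 93.2%, and Meis1, a homeobox gene active in stem cells, from 9.52% to 11.5%. The housekeeping genes Actb and Gapdh had no interval in any library. All 50 developmental regulators of other tissues were called in each library, as were all 39 Hox genes except in WT MET 2, where 31 were called and Hoxa5, Hoxb4 to Hoxb9 and Hoxb13 were not.

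**Figure D1:**
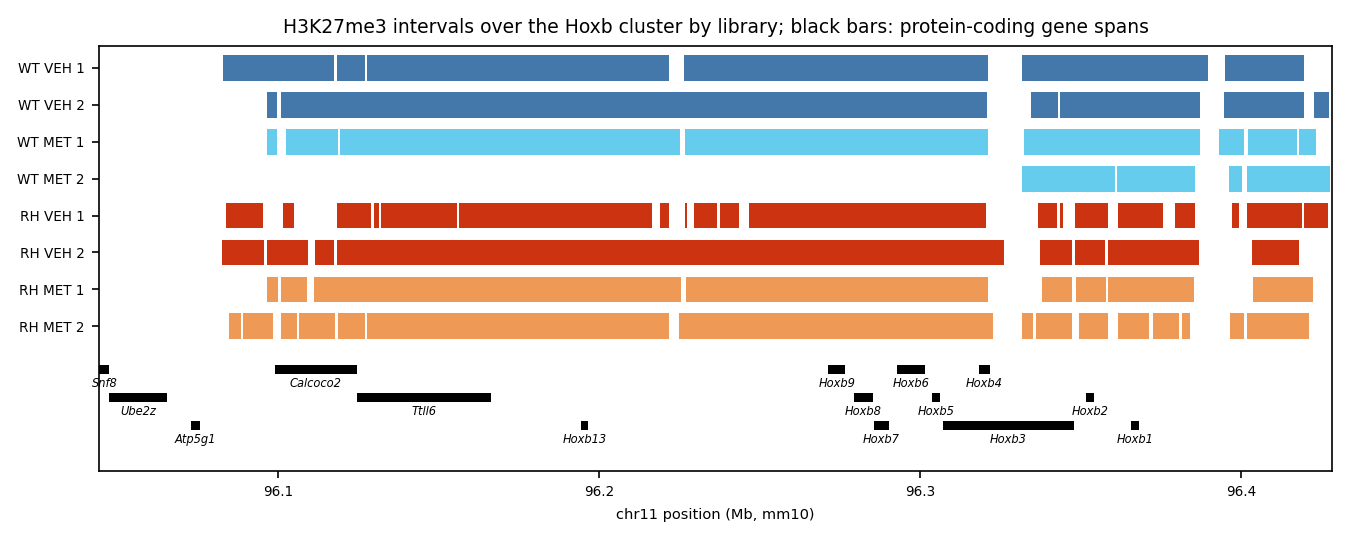
Intervals by library (boxes, coloured by group) along mm10 position in Mb over the Hoxb cluster on chromosome 11, with protein-coding gene spans in black. A region of 243.6 kb (chr11:96082401–96326000) holds intervals in 7 libraries and none in WT MET 2.

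The blood lineage lists were partly marked. Per library, intervals lay in 19 to 25 of 30 stem cell and self-renewal genes, 8 to 14 of 28 myeloid genes, 5 to 9 of 24 erythroid and megakaryocyte genes and 15 to 17 of 30 lymphoid genes. These counts need only 1 bp of overlap and do not rank the lists by cover. In the same order, 5.34% to 8.57%, 9.02% to 17.4%, 5.08% to 11.6% and 17.2% to 36.8% of the gene spans were covered. Intervals lay in 4 to 5 of 15 mast cell, basophil and eosinophil genes and in 13 to 14 of 20 stromal and endothelial genes, lists of other cells that the enrichment could hold. Inflammatory genes gave 6 to 11 of 30, cell cycle inhibitors and tumour suppressors 6 to 7 of 16, and imprinted genes 15 to 18 of 20. Mitochondrial complex I genes gave 1 to 4 of 30, methionine and one-carbon cycle genes 7 to 9 of 29, the histone and DNA methylation machinery 6 to 8 of 28, and housekeeping genes 0 to 3 of 30. Of 21887 protein-coding genes, 5438 were called in all 8 libraries, 8598 in at least 1 and 13289 in none.

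The 118629 intervals formed 18556 regions covering 257 Mb, the largest 530 kb wide. All 8 libraries called 6597 regions (35.6%), with a median width of 16.2 kb, and 4629 regions (24.9%) were called in 1 library, with a median width of 3.6 kb. Covered length was 143 ± 2.14 Mb in WT VEH, 167 ± 26.9 Mb in WT MET, 118 ± 53.1 Mb in RH VEH and 127 ± 6.44 Mb in RH MET (SD, n = 2 each). RH VEH 1 covered 80.0 Mb and RH VEH 2 covered 155 Mb, so that the spread within this group exceeded the differences between groups. The median summit height, the authors' own value, was 12 in RH VEH 1 and 14 to 17 in the other libraries.

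**Figure D2:**
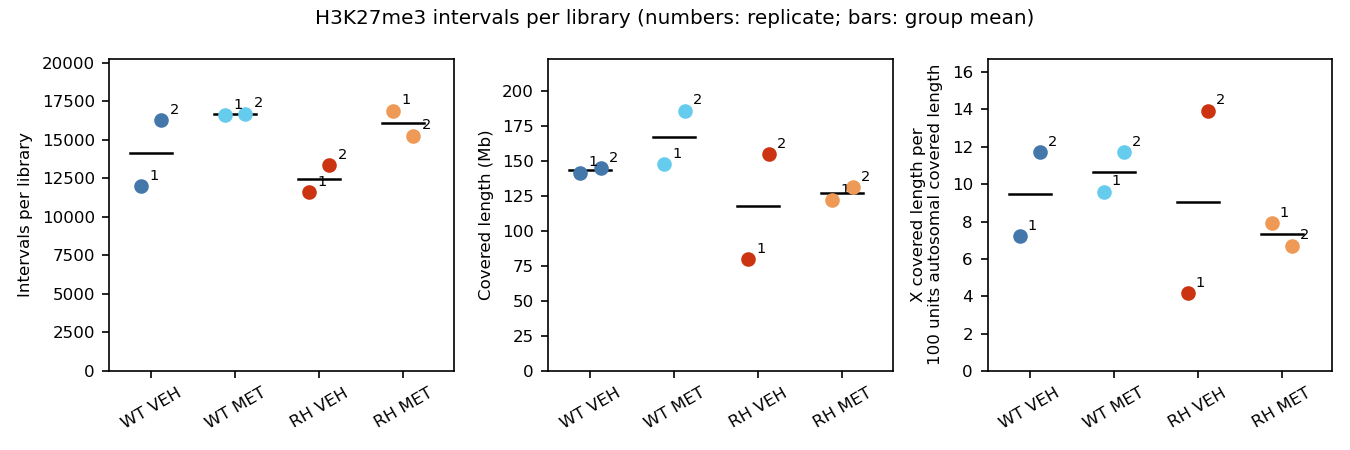
Intervals per library, covered length in Mb and covered length on the X chromosome per 100 units of autosomal covered length, by group; each point is a library labelled with its replicate number and each bar is a group mean. RH VEH 1 is lowest in all panels, with 11620 intervals, 80.0 Mb and 4.19 on the X chromosome, while RH VEH 2 has the highest X value, 13.9.

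Libraries of the same group were about as alike as libraries of different groups over all 8 libraries. The Jaccard index of covered base pairs averaged 0.560 over the 4 pairs within groups (0.456 to 0.598) and 0.559 over the 24 pairs between groups (0.402 to 0.611). The index also falls where covered lengths differ, and these ran from 80.0 Mb in RH VEH 1 to 186 Mb in WT MET 2. RH VEH 1 overlapped least with the others, with a mean index of 0.480, which need not mean that its intervals lay at other places. Without it the indices were 0.595 within groups (3 pairs, 0.587 to 0.598) and 0.584 between groups (18 pairs, 0.538 to 0.611), and without RH VEH 2 they were 0.595 and 0.549, differences that were not tested. Pairs of the same genotype exceeded pairs of different genotypes by 0.0155 (exact permutation over 35 splits, one-sided p = 0.114), and pairs of the same treatment differed from pairs of different treatments by -0.00561 (exact p = 0.629). Without RH VEH 2 the genotype value was 0.0411 with an exact p of 0.0286, the smallest these splits can give. It was 0.00643 without RH VEH 1 and turned to -0.00104 without WT MET 2.

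The mutant cells were compared with wild-type cells under vehicle, to ask what the R878H allele changes in the absence of drug. Kit, the stem cell factor receptor by which the cells were enriched, carried an interval at the lower-coordinate end of its span in both WT VEH libraries and neither RH VEH library (chr5:75574987–75656722; 7.24% ± 0.173 of the span covered in WT VEH, SD, n = 2). Of 14 callable myeloid genes, 2 also carried an interval in both WT VEH and neither RH VEH library, Csf3r, the receptor for granulocyte colony-stimulating factor (25.5% ± 21.7), and Mpo, the neutrophil granule enzyme myeloperoxidase (39.7% ± 15.97). Dntt, the lymphoid enzyme that adds nucleotides at V(D)J junctions, carried an interval in both RH VEH libraries and neither WT VEH library (13.6% ± 4.21). No other list gene separated these groups.

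Across the genome, 462 regions carried an interval in both WT VEH and neither RH VEH library, and 85 the reverse, of 14064 regions called in at least 1 of the 4. Among the widest of the 462 were a 28.4 kb region over Dbh, which makes noradrenaline, and Sardh, a mitochondrial sarcosine dehydrogenase (chr2:27160201–27188600; 19.2 ± 9.33 kb covered in WT VEH, SD, n = 2), and a pair of regions within D430041D05Rik (chr2:104243801–104271000 and chr2:104307401–104334400). Others lay near Gpam, an acyltransferase of triglyceride synthesis, Col13a1, a transmembrane collagen, and Tmem132e. Among the widest of the 85 were regions near the forkhead gene Foxf2 (chr13:31637601–31673800; 17.4 ± 21.8 kb in RH VEH) and the splicing regulator gene Mbnl3, and over the adhesion receptor gene Adgrv1, the kallikrein gene Klk15 and the bone morphogenetic protein receptor gene Bmpr1a. The changed regions were weak in their own lists, with median summit percentiles of 25.1 and 29.0 against 74.4 and 70.4 for regions called in all libraries. On protein-coding genes the counts were 188 and 34 of 7831.

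The other splits of these 4 libraries gave 54 and 949 regions (number 1 libraries against number 2 libraries) and 189 and 209, and 2 libraries against 2 cannot give an exact p below 0.333. By Fisher's exact test none of the lists was enriched among changed genes after adjustment over the 90 tests of all 3 comparisons, where the smallest adjusted p was 1 and 2 tests had an unadjusted p under 0.05, one of them the 2 myeloid genes here (p = 0.0431). With an equal number of intervals per library the region counts were 312 and 171. With a minimum summit height of 15 they were 362 and 6, and of the named list genes Mpo alone separated the groups. This minimum kept 38.8% of the intervals of RH VEH 1 and 62.1% of those of WT MET 2. Mpo only just met it, with a summit height of exactly 15 in both WT VEH libraries. Of the 10 widest regions each way, 6 of WT VEH and 5 of RH VEH still separated the groups with an equal number, among them those at Tmem132e, D430041D05Rik, Foxf2 and Bmpr1a, and 0 and 0 did with the minimum summit height. Leaving out WT VEH 1, WT VEH 2, RH VEH 1 or RH VEH 2, so that the remaining library stood for its group, gave 2417, 1093, 656 and 1511 regions in WT VEH alone against 154, 479, 1064 and 365 in RH VEH alone, a turned direction without RH VEH 1, and 542, 449, 280 and 662 against 63, 163, 254 and 77 genes.

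Metformin was compared with vehicle in R878H cells, the setting the series title is about. Irf1, an interferon-responsive transcription factor, carried an interval over the lower-coordinate part of its span in both RH MET libraries and in no other library (chr11:53770014–53778374; 44.1% ± 5.07 covered, SD, n = 2). Mllt3, a maintenance factor of hematopoietic stem cells (0.988% ± 0.00188), and Msi2, an RNA-binding protein of self-renewal (1.03% ± 0.261), each had a short interval in both RH MET libraries and in no other. Csf3r (11.1% ± 6.44) and Vwf, the megakaryocyte and endothelial von Willebrand factor (4.49% ± 1.06), carried intervals in both RH MET and neither RH VEH library. Dntt carried none in RH MET and was the only list gene to separate the groups in that direction.

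In all, 739 regions carried an interval in both RH MET and neither RH VEH library, and 54 the reverse, of 14806. The widest of the 739 included those over Dbh and Sardh (6.0 ± 3.39 kb covered in RH MET, of a region of 28.4 kb), both regions of D430041D05Rik and those near Col13a1 and Tmem132e, all of which are named above as called in both WT VEH and neither RH VEH library. Width was that of the region merged over all 8 libraries, which favours regions that many libraries called. The match with the widest WT VEH regions is therefore set in part by this choice. Further wide ones lay over the melanosome transporter gene Slc45a2 (chr15:11004601–11028800; 7.1 ± 6.93 kb) and near the nuclear kinase gene Vrk1. The widest of the 54 included those over Tmsb4x, which encodes the actin-binding thymosin beta 4, Frmpd4, Xkr6, the brush border myosin gene Myo7b, Obi1, the olfactory receptor gene Olfr332, the exchange factor gene Dock3 and Fam83c. Median summit percentiles were 32.0 for the 739 and 18.1 for the 54. Protein-coding genes gave 236 and 16 of 7887.

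The other splits of these 4 libraries gave 151 and 406 regions and 76 and 603, and the smallest exact p is again 0.333. With an equal number of intervals per library the counts were 361 regions in RH MET and 202 in RH VEH. Mllt3 and Csf3r then no longer separated the groups. With the minimum summit height the counts were 801 and 0, and of the named genes Vwf alone separated the groups. Vwf only just met the minimum, with a summit height of exactly 15 in both RH MET libraries. Of the 10 widest regions each way, 3 of RH MET, the one near Tmem132e included, and 3 of RH VEH, those over Xkr6 and Fam83c included, still separated the groups with an equal number, and 1 and 0 did with the minimum summit height. Leaving out RH VEH 1, RH VEH 2, RH MET 1 or RH MET 2 gave 1038, 1978, 2026 and 2438 regions in RH MET alone against 986, 266, 224 and 136 in RH VEH alone, and 369, 711, 469 and 626 against 306, 55, 80 and 52 genes.

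Metformin was also compared with vehicle in wild-type cells. Dntt carried an interval at the lower-coordinate end of its span in both WT MET and neither WT VEH library (17.9% ± 0.467 covered, SD, n = 2), the opposite of its calls in R878H cells. So did Tek, the angiopoietin receptor of stem and endothelial cells (1.04% ± 0.104). No list gene was called in both WT VEH and neither WT MET library. The 718 regions called in both WT MET and neither WT VEH library included wide ones over Gnl3l, a nucleolar GTPase gene (chrX:150966601–150998800; 16.1 ± 2.69 kb), Dzank1, Grpr, the gastrin-releasing peptide receptor gene, Sobp and the predicted genes Gm9195 and Gm30500, and near Mbnl3. The 85 regions of the reverse kind included those over Frmpd4, the mitotic helicase gene Ercc6l and Tlr8, a sensor of RNA in endosomes, and those nearest to Grpr and Atp13a4. The Frmpd4 region here (chrX:168073801–168090800) is another one than that named for R878H cells (chrX:168321401–168343000). Neither of them separated the treatments in the other genotype. The median summit percentiles below are for the 718 and the 85. These percentiles were 26.2 and 20.1.

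These counts were out of 16431 regions, and 184 and 43 of 8236 protein-coding genes went the same 2 ways. The other splits gave 110 and 665 regions and 176 and 385, with 0.333 again the smallest exact p. With an equal number of intervals the counts were 312 in WT MET and 190 in WT VEH, and with the minimum summit height 614 and 6, where neither Dntt nor Tek separated the groups. Of the 10 widest regions each way, 1 of WT MET and 2 of WT VEH still separated the groups with an equal number, none of them at a gene named here, and 0 and 0 did with the minimum summit height. Leaving out WT VEH 1, WT VEH 2, WT MET 1 or WT MET 2 gave 1054, 2131, 2561 and 2067 regions in WT MET alone against 1118, 419, 201 and 332 in WT VEH alone, a turned direction without WT VEH 1, and 327, 571, 507 and 379 against 207, 220, 108 and 136 genes.

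**Figure D3:**
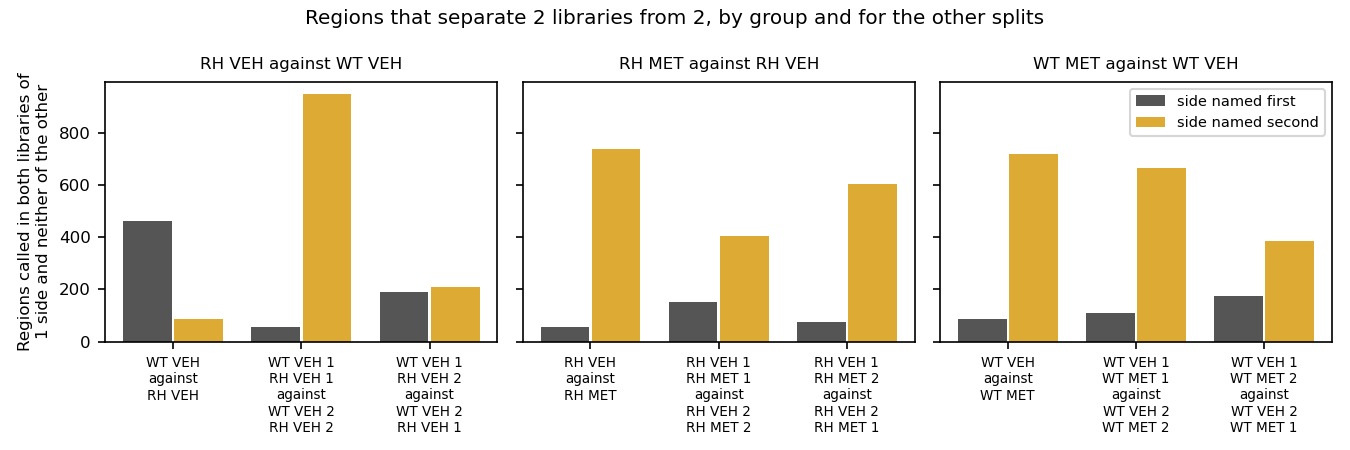
Regions called in both libraries of the side named first and neither of the side named second (dark bars), and the reverse (light bars), for each comparison and for the other splits of its 4 libraries; the vertical axis is the number of regions. The split of number 1 against number 2 libraries under vehicle gives 949 regions on its second side, above the 462 of WT VEH against RH VEH, while 739 and 718 with metformin are the highest of their panels.

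**Figure D4:**
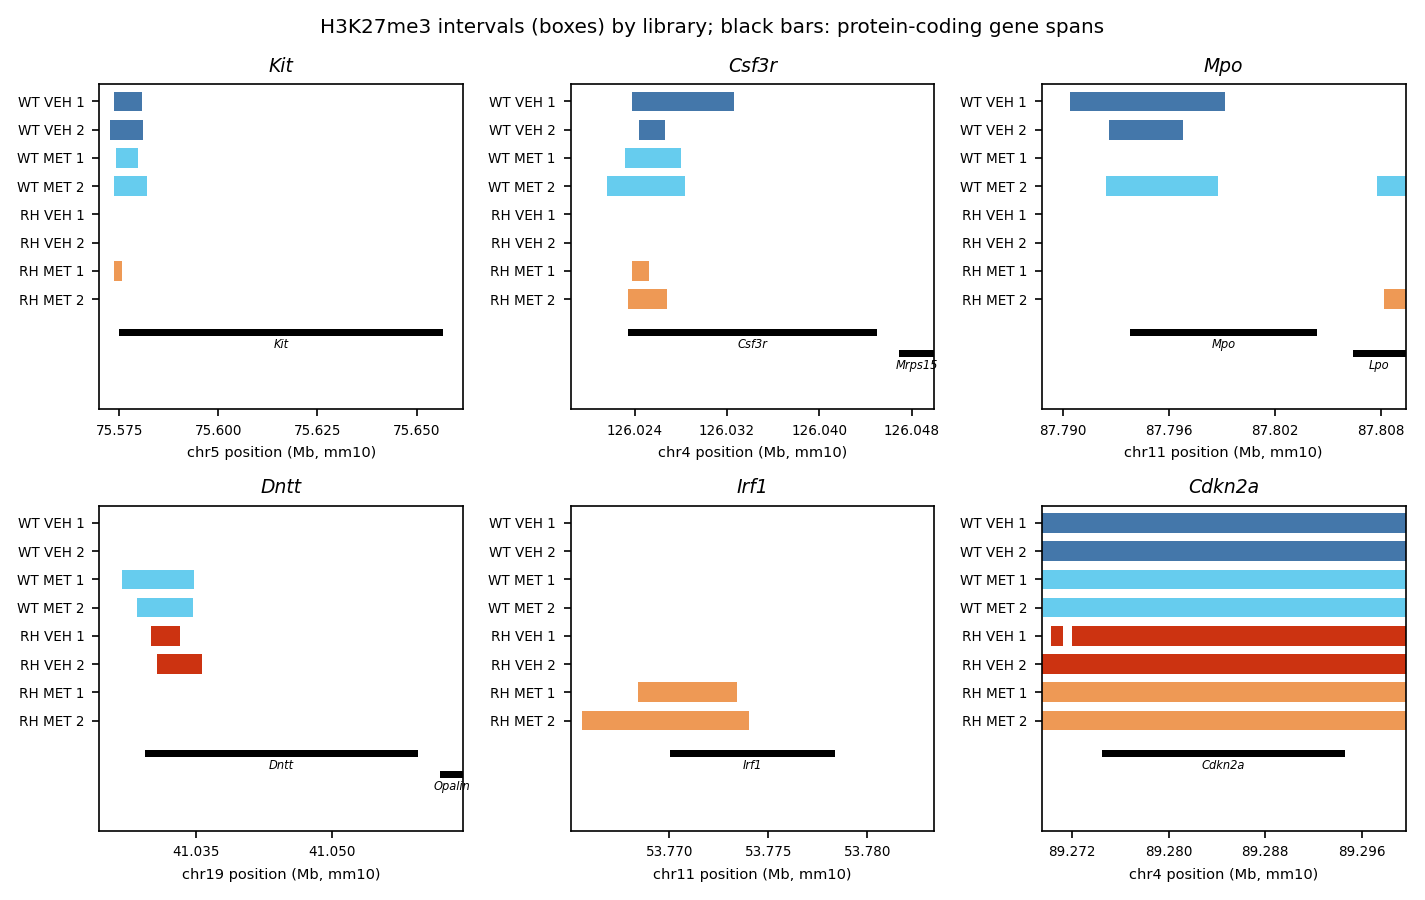
Intervals by library (boxes, coloured by group) along mm10 position in Mb at Kit, Csf3r, Mpo, Dntt, Irf1 and Cdkn2a, with protein-coding gene spans in black. Cdkn2a is covered in all 8 libraries, Kit has intervals in 5, Csf3r in 6, Mpo in 3, Dntt in 4 and Irf1 in 2.

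The regions missing from R878H cells under vehicle were then followed into metformin, to ask whether the drug moves the mutant profile back toward wild type. Of the 462, 169 (36.6%, exact binomial interval 32.2% to 41.2% for counting error only) were called in both RH MET libraries, among them those at Dbh and Sardh, D430041D05Rik, Col13a1 and Tmem132e, and 118 (25.5%) in neither. Of these named regions, the one near Tmem132e alone still separated RH MET from RH VEH with an equal number of intervals, and none did with the minimum summit height. Kit was called in RH MET 1 and not RH MET 2, and Mpo in neither. Of all 7433 regions absent from RH VEH, 9.94% were called in both RH MET libraries. Both WT MET libraries called 259 of the 462 (56.1%). Of the 85 regions called in both RH VEH and neither WT VEH library, 17 were called in neither RH MET library and 37 in both.

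The 462 had 2 WT VEH calls by definition, and regions that more of the other libraries called were also called more often in RH MET. Among regions absent from RH VEH that 3 of the 4 WT libraries called, both RH MET libraries called 49 of 146 (33.6%) where both WT VEH libraries were among the 3 and 142 of 519 (27.4%) where 1 was. Among those that 2 WT libraries called, they called 5 of 57 (8.77%) where both were vehicle libraries, 103 of 823 (12.5%) where 1 was and 58 of 438 (13.2%) where neither was. These differences were not tested. The other 259 of the 462 were called in all 4 WT libraries and have no regions to compare with at that number of WT calls. They held 115 of the 169 regions called in both RH MET libraries (44.4% of the 259). Regions are not independent replicates, and the RH VEH libraries enter both lists. Independent lists would share 20.8 of all 16414 regions called in the 6 WT VEH, RH VEH and RH MET libraries, and 64.5 of the 5291 that RH VEH lacked. Taking each pair of these 6 libraries in turn as the pair that lacks a region the other 4 call gave 74.3 regions on average, with 334 for WT VEH 1 with RH VEH 1, above the 169 of RH VEH, and 159 for RH VEH 1 with RH MET 2. The share was 23.0% in 2000 bp bins, 20.9% where intervals had to cover 50% of a region and 61.3% with the minimum summit height, and it was 16.8% without WT VEH 1, 22.0% without WT VEH 2, 56.9% without RH VEH 2 and 60.1% without RH MET 2. The minimum summit height kept 38.8% and 47.6% of the intervals of RH VEH 1 and 2, and 50.8% and 53.2% of those of RH MET 1 and 2. It thereby favours regions absent from RH VEH and called in RH MET, which can raise the share.

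Both treatments of a genotype, and both genotypes of a treatment, were last pooled as 4 libraries against 4. The stem cell and self-renewal list averaged 23.25 called genes with metformin and 20.25 with vehicle, and the erythroid and megakaryocyte list 8.25 and 6.0, each at the smallest possible exact p of 0.0286, which did not pass adjustment over the lists (adjusted p = 0.214). Of all protein-coding genes, metformin libraries called 7162.75 on average and vehicle libraries 6644.5 (exact p = 0.0571, adjusted p = 0.343). Part of the list differences may be this general one. Myeloid genes averaged 10.75 called in RH and 13.25 in WT libraries (exact p = 0.114, adjusted p = 0.857), and their spans were covered over 11.97% ± 2.54 and 15.7% ± 1.37 (SD, n = 4; exact p = 0.0571, adjusted p = 0.429). Lower cover in RH was not particular to them. Stromal and endothelial spans had 12.7% and 15.6%, and erythroid and megakaryocyte spans 8.36% and 10.7% (exact p = 0.0857 each). Only the Hox, stem cell and inflammatory lists were covered more in RH. None of the 15 lists passed the threshold in either comparison by the exact test, which 1 list could do only if at least 9 reached the smallest p together, and those 2 treatment tests alone had an unadjusted p under 0.05. With an equal number of intervals per library, the stem cell list averaged 22.75 and 20.25 (exact p = 0.0286, adjusted p = 0.429) and the erythroid and megakaryocyte list 7.25 and 6.0 (exact p = 0.114).

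Metformin libraries held 3043.75 more intervals than vehicle libraries on average (16350.5 against 13306.8, n = 4 each; exact p = 0.0571, adjusted p = 0.343) and 16.4 Mb more covered length (exact p = 0.543), and without RH VEH 1 the covered length differed by -0.343 Mb. RH libraries differed from WT libraries by -1109.75 intervals (exact p = 0.543, n = 4 each) and by -32.9 Mb (exact p = 0.114). A total of 58 regions were called in all 4 metformin and no vehicle library and 1 the reverse, and 39 were called in all 4 WT and no RH library and 5 the reverse. These counts were 17 and 8, and 25 and 6, with an equal number of intervals per library. Of the 35 splits of the libraries, the real one included each time, 4 separated as many regions as treatment did (59 in all) and 8 as many as genotype did (44). The 58 are the overlap of the 718 and the 739, for which independent lists would give 28.6 over all 18556 regions and 44.4 over the 11959 not called in all 8 libraries, if every region were called as readily as another. Of the 4492 regions called in no vehicle library, both WT MET libraries called 438 and both RH MET libraries 287, for which independent lists would give 27.98 under the same condition. Regions were not called equally readily, with 4629 called in 1 library and 6597 in all 8. An overlap of 58 above these values therefore does not show an effect of metformin. In all, 6 and 5 regions went opposite ways in the genotypes. Leaving out libraries in turn gave 94, 172, 126, 100, 75, 106, 125 and 155 metformin regions without WT VEH 1, WT VEH 2, WT MET 1, WT MET 2, RH VEH 1, RH VEH 2, RH MET 1 and RH MET 2, and 160, 77, 73, 58, 45, 79, 107 and 75 wild-type regions.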

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

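The tests of wide intervals and of a width limit at the missing strong regions were chosen only after the result was seen, as were the bounds of a strong region. Totals and list coverage were screened for a library that stood farther from the other 3 of its class than Dixon's test allows for 4 values. Of 84 such tests 11 were positive, where 4.2 are expected by chance, and several of them concern the same library.

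WT MET 2 covered 185.857 Mb, against 142 to 148 Mb in the other WT libraries. The same library covered 73.4% of Hox gene spans (90.5% to 93.1% in the other WT libraries), 36.8% of lymphoid spans (28.1% to 29.4%), 5.66% of methionine and one-carbon cycle spans (3.58% to 3.92%) and 14.46% of imprinted spans (13.5% to 13.6%), and among metformin libraries 7.01% of mast cell, basophil and eosinophil spans (5.01% to 5.27%). WT VEH 1 held 12009 intervals, against 16259 to 16694 in the other WT libraries, and covered 1.96% of complex I spans, against 0.681% to 0.781% in the other vehicle libraries. RH VEH 1 covered 8.63% of stromal and endothelial spans (14.8% to 15.8% in the other vehicle libraries) and 12.1% of imprinted spans (13.5% to 13.6%). RH MET 2 covered 12.04% of myeloid spans, against 15.2% to 15.6% in the other metformin libraries.

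Dntt was called in 4 libraries, both WT MET and both RH VEH, so that its calls went one way with metformin in wild-type cells and the opposite way in R878H cells. This difference was not tested for Dntt alone. The other protein-coding genes with such crossed calls were Kdm3b, a histone H3 lysine 9 demethylase, in the same libraries, and Hilpda, Saa4 and Olfr159 in the opposite ones, chosen after their values were seen. The 5 genes do not exclude chance, since 31 of the 35 splits of the 8 libraries separated as many protein-coding genes and the highest other split separated 32.

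The low Hox coverage of WT MET 2 came from absent intervals at a strongly marked place. In the other 7 libraries the Hoxb region chr11:96082401–96326000, with Hoxb4 to Hoxb9 and Hoxb13, had summit heights of 43 to 89. In all, 9 regions were called at or above the 75th percentile of summit height in 7 libraries and not called in the remaining one, among them the receptor tyrosine kinase gene Ret (chr6:118184201–118209000) in WT MET 2. By definition the other library of the same group called each of these. No region that strong in 6 libraries was missing from both libraries of a group (0 regions), which argues against loss of such regions in 1 group alone. A strong region lost from all 4 libraries of a genotype or treatment could not enter this count, so it cannot decide on such an effect. A limit on interval width is argued against, since in 7 of the 9 cases the library kept an interval wider than the whole gap that held the missing region (411.8 kb in WT MET 2, against a gap of 298.6 kb at Hoxb), and 2 of the 9 regions were 10.6 and 8.2 kb wide, under the median of 12.8 kb for regions called in 7 libraries. Loss of wide intervals for another reason stays open as a candidate explanation. Of the 9, 8 fell in the 3 libraries with the widest median intervals (WT VEH 1, WT MET 2 and RH VEH 2), as many as in 1 of the 56 sets of 3 libraries (share 0.0179, the smallest possible). This test was chosen after those counts were seen, so its share cannot decide, and the region of 10.6 kb is among the 8. No step that would lose wide intervals is given in the sources used here, and no read coverage was analysed here to show whether the mark is present.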

How the results depend on the processing

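Use of the minimum summit height on genes had not been planned. The equal-number alternative was chosen only after the data were seen, and so was the flank of 2500 bp. The order of equal summit heights in the former was also changed after its first values had been seen, and over 10 other orders it gave 307 to 319 WT VEH and 166 to 179 RH VEH regions, 192 to 208 RH VEH and 341 to 360 RH MET regions, and 170 to 186 WT VEH and 303 to 320 WT MET regions, with the larger side the same in each. With file order and the regions of all intervals kept, close to how this alternative was first explored, the counts were 309 and 157, 204 and 349, and 160 and 298. Under every alternative that used all 8 libraries, the WT VEH side stayed above the RH VEH side and the metformin side above the vehicle side. No gene list passed the threshold, which says little of stability, since 9 of the 15 would have to reach the smallest p together. Differences in interval number kept their direction with any 1 library left out (2481.5 to 4027.83 for metformin, -2234.58 to -225.167 for RH). The Jaccard difference by treatment turned to 0.0115 (exact p = 0.143) with summit heights at or above 15, and the cause was not tested.

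In 2000 bp bins, which count wide regions many times by construction, the regions were 4808 and 619 for WT VEH and RH VEH, 3260 and 908 for RH MET and RH VEH, and 5427 and 1427 for WT MET and WT VEH, with 569 in WT, 21 in RH, 201 in MET and 19 in VEH over 4 against 4. With an equal number of intervals, RH VEH against WT VEH gave 171 regions in RH VEH, RH MET gave 361 and its vehicle 202, WT MET gave 312 and its vehicle 190, and 4 against 4 gave 25 in WT, 17 in MET and 8 in VEH. Where intervals had to cover 50% of a region, 170 regions were in WT VEH and not WT MET, and 4 against 4 gave 89 in WT, 2 in RH, 29 in MET and 2 in VEH. With summit heights at or above 15, 6 regions were in RH VEH and not WT VEH, 0 in RH VEH and not RH MET, 6 in WT VEH and not WT MET, 1 in RH and 0 in VEH. On chromosomes 1 to 19 alone, 0 regions were in VEH. The share of the 462 regions called in both RH MET libraries was 23.0% in bins, 25.3% with an equal number, 20.9% with 50% cover and 61.3% with summit heights at or above 15. The causes of these moves were not tested.

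With a library left out, its partner alone stood for the group, which raises counts by construction. The ranges were 465 to 2417 regions for WT VEH against RH VEH and 85 to 1064 for the reverse, 750 to 2438 for RH MET against RH VEH and 54 to 986 for the reverse, and 720 to 2561 for WT MET against WT VEH and 85 to 1118 for the reverse. Over 4 against 4 they were 45 to 160 in WT, 7 to 26 in RH, 75 to 172 in MET and 1 to 8 in VEH, and the share ranged from 16.8% to 60.1%. Covered length by treatment ranged from -0.343 Mb, without RH VEH 1, to 24.7 Mb. The Jaccard difference ranged from -0.0157 to 0.00614 by treatment, above 0 without WT VEH 1, WT VEH 2 or RH VEH 2, and from -0.00104 without WT MET 2 to 0.0411 without RH VEH 2 by genotype.

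Deviations of same-numbered libraries correlated by only -0.0133 to 0.0754, and the labels do not say whether the replicate numbers pair libraries across groups. Under vehicle, number 1 against number 2 libraries separated 1003 regions, against 547 for the genotypes. A shared difference by number there stays open and was not tested. With the number as a block, both pairs moved together in 462 and 85, 739 and 54, and 718 and 85 regions, which is the main count by construction. The pairs of number 1 and number 2 alone gave 2241 and 2745 regions for WT VEH against RH VEH and 944 and 1317 for the reverse, 4179 and 2387 for RH MET against RH VEH and 411 and 1757 for the reverse, and 3676 and 2964 for WT MET against WT VEH and 805 and 1592 for the reverse. Sign flips within 4 pairs cannot give an exact p below 0.125, nor permutation within the other factor one below 0.0556, and the 3043.75 more intervals with metformin stood at both floors, so that neither test could have changed a call. Promoter windows and values per region were not run. Without reads per library, an absent interval cannot be told from one below the caller's limit.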

Other observations

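The equal-number test, the test without weak intervals and the tests of the covered share of every chromosome and of genotype or metformin on the X chromosome, and the values there without a library, were chosen only after the results were seen, and the reading of both tests over the 35 splits, which had been set before, was written after. The X chromosome varied most between libraries. Its covered length per 100 units of autosomal covered length was 7.23 and 11.7 in WT VEH, 9.60 and 11.7 in WT MET, 4.19 and 13.9 in RH VEH and 7.90 and 6.71 in RH MET, and no library had an interval on the Y chromosome. Regions on X that separated groups included those over Tmsb4x, Frmpd4, Tlr8 and Gnl3l, named above.

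The highest X value was 3.33 times the lowest, against at most 1.15 on any autosome, which argues against libraries differing in how much of every chromosome was called. After matching regions on their summit percentile in the other libraries, the ratio of observed to expected X calls differed by 2.02 times, from 0.80 in RH MET 2 to 1.62 in RH VEH 2, against at most 1.12 on autosomes, but by 1.58 times without RH VEH 2, and it was 0.898 in RH VEH 1, so that weak X intervals dropping out first stays open as a cause. The lowest and highest X values were both in RH VEH, a pair that differed by 3.33 times while group means differed by at most 1.46 times. Without RH VEH 2 the widest pair differed by 1.62 and the group means by 2.54 times. RH VEH was then RH VEH 1 alone, the lowest library, so that this removal cannot decide the question. An effect of genotype or metformin stays open too. A different share of cells with an inactive X chromosome, as mixed donor and recipient cells could give, is a biological explanation that was not tested.

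More regions were called on the WT VEH side than on the RH VEH side, and more with metformin than with vehicle, and libraries that differ in how many intervals they call, for a technical or a biological reason, could give this. A minimum summit height of 15 cannot show whether weak intervals alone differ, because it left the libraries with 4505 to 10367 intervals, from 11620 to 16879 before, and the larger side then held 98.4% instead of 84.5% of the changed regions for RH VEH against WT VEH, 100% instead of 93.2% for RH MET against RH VEH and 99.0% instead of 89.4% for WT MET against WT VEH. With an equal number of intervals per library the larger count over the smaller fell from 5.44 to 1.82 and from 13.7 to 1.79 in the first 2 of these comparisons. These lay below the 2.42 and 3.10 of other splits of the same libraries, and likewise under all 10 other orders of equal heights. In the first this cannot decide, because with all intervals another split, with 54 and 949 regions, was already more one-sided than the groups. Equal numbers also left covered length unequal, by -23.4 Mb for RH against WT. In the last comparison the ratio fell from 8.45 to 1.64, above the 1.61 of another split and at or below it in 1 of 10 other orders. Number and metformin cannot be told apart there by so small a margin. Over 4 against 4, chance is not excluded for the 44 regions that separated the genotypes, a number that 8 of the 35 splits reached. Nor is it for the 59 that separated the treatments, which 4 of the 35 reached. Both counts of splits include the real one. The highest other split, WT VEH 1, RH VEH 1, RH VEH 2 and RH MET 2 against the rest, separated 111. That split parts the 4 libraries with the fewest regions called (8016 to 11027) from the 4 with the most (11784 to 13197), and an effect of genotype or metformin beneath these differences stays open.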
